A study of Sus scrofa with 2 samples.

How the data were processed

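RNA from the hippocampus of Rongchang piglets (Sus scrofa) was sequenced on an Illumina HiSeq instrument, per the labels, in 1 control sample and 1 iron dextran sample. Per the labels' protocols, tissue was frozen in liquid nitrogen, total RNA was extracted with RNAiso Plus and libraries followed the standard Illumina preparation. The dose, the age and sex of the piglets and the number of animals are not given in the sources used here. The values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) in a table deposited by the authors, with 1 row per Ensembl pig gene ID and 1 column per sample. Columns were assigned by the letter that the column name shares with the sample title and with both names in the sample description. The submitters' processing notes name cutadapt 1.2.1, which trims adapters from reads, TopHat, a spliced aligner, and the pig genome builds Sscrofa10.2 and susScr3. The version of TopHat, the program that made the FPKM values, the gene annotation, the use of strand, and how the material behind the 2 names of a sample was combined are not given in the sources used here. FPKM divides by gene length and library total, so a few abundant genes can shift all others: the 10 highest IDs took 36.7% of the control total and 34.0% of the iron dextran total. Small nucleolar RNAs are shorter than most library fragments, and values of near-identical paralogs such as globins and ribosomal proteins depend on how shared reads were assigned, so both are uncertain.

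Gene symbols came from a table that pairs Ensembl IDs with names, which matched 11804 of 25322 IDs; 39 list symbols were updated to their current names. No annotation of the build was used, so no coordinates or gene lengths are given. In total, 7870 IDs were listed at 0 in both samples.

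Depth was examined on 690 genes that were above 0 in both samples and had a control FPKM under 0.1. Of their ratios of iron dextran to control, 194, 125 and 45 lay within 0.05 log2 units of 1, 2 and 0.5 times a common value, which is 52.8% of these genes where an even spread from −2 to 2 would give 7.5%. The common value was taken at the peak of these same ratios, so part of this excess follows from that choice. The limit on low values was set on control alone, which can favour ratios above the common value. Read as whole fragments, 1 fragment in iron dextran was worth 0.947 of 1 in control, a relative depth of 1.06. The absolute depth stayed unknown, so no counting interval or detection limit is given.

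For each gene the difference of log2(FPKM + 1), iron dextran minus control, was computed; the pseudocount of 1 understates the change of low genes. Genes needed a mean FPKM of at least 1 (12557 genes, 8403 with a symbol). A gene counted as higher or lower from 2-fold on this scale, and a member of a gene list from 1.5-fold. With 1 sample per group no test and no p-value across genes was made. For 42 lists of gene groups and cell type markers, the median difference was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these libraries and not the conditions. Genes named are the 12 with the largest difference each way among genes with a symbol that passed the rule of size (10 were lower), 14 iron, blood and brain genes given whatever their values, and up to 4 members per list with the largest absolute difference; some genes that this rule takes are not reported here. TAP1, PSMB8, PSMB9, RPS21 and COX10, named because they were listed at 0, and OASL, NFKBIA, SGK1 and PER1, named because they went against their list, were chosen after their values were seen.

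The comparison, the rules of size, the lists, the rule for named genes and most alternatives were set before the data were examined. Set after the differences had been seen were the limits of percentile 2.5 and 97.5, the minimum of 3 measured members, the 95% interval of a list median from binomial order statistics (the range below 6 members), the check of depth, the choice of IDs without a symbol (mean FPKM of at least 20), and a list of antigen presentation genes. A list of Y-linked genes, also added then, had 0 matched IDs and was not used. The symbol updates were made after it was known which list symbols had a match, and before any list difference was computed.

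Alternatives were pseudocounts of 0.1 and 0.01, no filter and a mean FPKM of at least 5, columns centred on their median, rescaled by a trimmed mean of M values (TMM; 30% of M values and 5% of A values trimmed per side) or scaled to the same total, folds of 1.5 and 4, and random lists not matched on expression. Added later were differences centred by expression bin, the counts without genes listed at 0 and the counts over genes with a symbol alone. Percentiles under alternatives used 2000 random lists. On simulated data with 12449 genes, the rule of 2-fold called 0 of 50 genes changed 1.5-fold, 13 of 50 changed 2-fold, 40 of 50 changed 3-fold and 48 of 50 changed 4-fold, and 0 unchanged genes. The simulated noise had the same spread, 0.193 log2 units, for every gene and no counting error. Few unchanged genes could pass 2-fold under it, so it does not show how often the rule errs in the real data. In a simulation of lists of 15 members among 12257 genes, 61 of 1000 unshifted lists fell outside the percentile limits, as did 40 of 40 lists shifted by 0.3. Members were drawn at random and had independent noise, so both counts follow largely from these settings. They do not show how often real lists, whose genes can vary together, fall outside. Smaller shifts were not simulated. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.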

Results

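Gene expression was measured by RNA sequencing in the hippocampus, a forebrain region needed for forming memories, of piglets of the Rongchang breed. The comparison asked how the hippocampal transcriptome differed between control piglets and piglets given iron dextran, a complex of iron and a sugar polymer that is injected into piglets against iron deficiency. Each group was 1 sample. The label of each sample lists 2 names and does not say whether these were animals, libraries or sequencing runs, and each sample had 1 value per gene. There was no spread between replicates to set a difference against, so no test was made and no difference given here has a replicate check. The table held 25322 gene IDs, of which 16727 were above 0 in control and 16865 in iron dextran. FPKM values summed to 924070 in control and 850165 in iron dextran, and the 13 mitochondrially encoded genes with a symbol took 29.5% and 29.0% of these totals. The number of fragments sequenced is unknown. If the steps between low values are read as whole fragments, the depth of the iron dextran sample was 1.06 times that of control.

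In the iron dextran sample, antiviral genes of the interferon response, globin genes and some glucocorticoid-responsive genes were higher than in control. Microglial markers had a median above those of random lists, with 1 of 11 members past 1.5-fold. LCN2, which encodes a protein that binds iron-carrying siderophores, was lower. Myelin, meningeal and cholesterol synthesis genes had medians below those of random lists, by small differences with no member past 1.5-fold. Here and below, counts of members past 1.5-fold are on the log2(FPKM + 1) scale, which understates the change of low genes. Most genes differed little. Of 12557 genes with a mean FPKM of at least 1, 96.1% lay within 1.5-fold on the log2(FPKM + 1) scale, with quartiles of the log2 difference at −0.12 and 0.14. By the rule of at least 2-fold, 93 genes were higher in iron dextran and 53 were lower. Of these, 38 were listed at 0 in control and 24 were listed at 0 in iron dextran. With those genes left out, an alternative added after the data had been seen, the counts were 55 and 29. An exact 0 in this table can be a failed estimate, since RPS21 and COX10, genes that every cell uses, were listed at 0 in both samples.

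**Figure D1:**
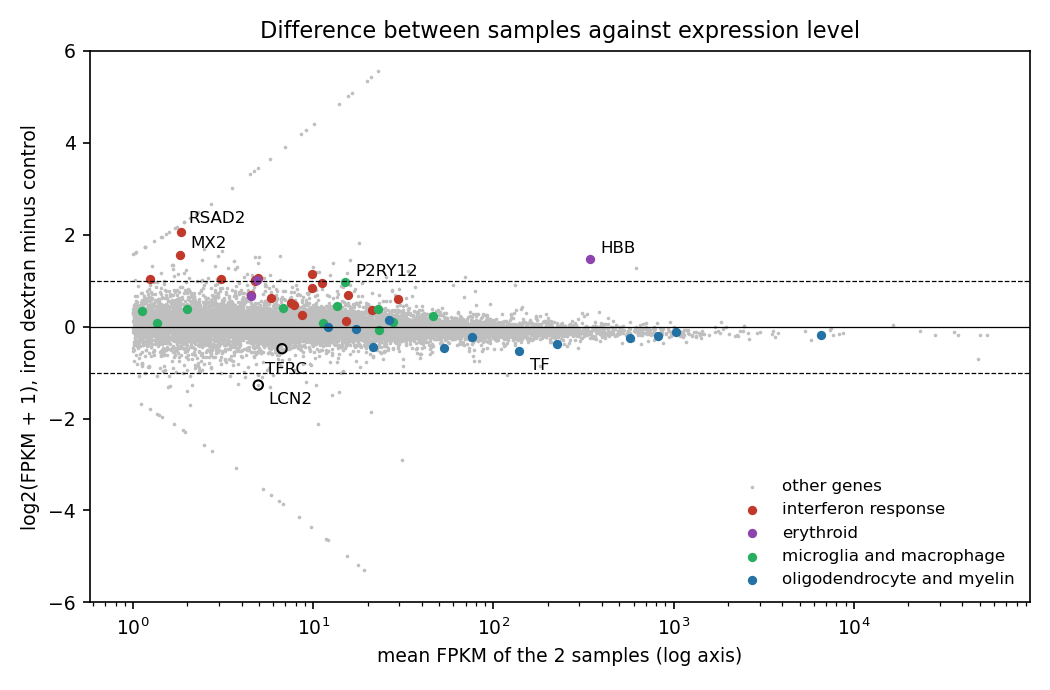
Difference in log2(FPKM + 1), iron dextran minus control, against the mean FPKM of both samples (log axis) for 12551 genes with a mean FPKM of at least 1; 6 genes beyond a difference of 6 either way are not drawn, dashed lines mark 2-fold, the straight diagonal rows of points are genes listed at 0 in 1 sample, and open circles mark TFRC and LCN2. The 19 interferon response genes (red) and 3 erythroid genes (purple) all lie above 0, and 11 of 12 oligodendrocyte genes (blue) lie below it.

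Of the 93 genes that were higher, 23 carried a symbol, and 7 of these belonged to the interferon list. RSAD2 (ENSSSCG00000008648), which encodes the antiviral protein viperin, had 0.0948 FPKM in control and 3.57 in iron dextran. MX2 (ENSSSCG00000012076), an interferon-induced GTPase, had 0.422 and 3.21 FPKM. HBB (ENSSSCG00000014725), the beta chain of haemoglobin, had 183 and 506 FPKM, a ratio of 2.76. GHSR (ENSSSCG00000020906), the ghrelin receptor, had 5.94 and 14.9 FPKM, a ratio of 2.503. ALDH3A1, an aldehyde dehydrogenase, had 1.78 and 5.59 FPKM, and IQCJ had 0.487 and 2.78. The small nucleolar RNA genes SNORA61, SNORA46, SNORD97, SNORA2C and SNORD17, and GP1BB, a subunit of a platelet surface receptor, were listed at 0 in control and had between 2.34 FPKM (SNORD17) and 31.1 FPKM (SNORA61) in iron dextran.

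Of the 53 genes that were lower, 10 carried a symbol. H1-3 (ENSSSCG00000001137), a linker histone, had 19.3 FPKM in control and 6.21 in iron dextran, a ratio of control to iron dextran of 3.12. This gene was not on the list of histones without a poly(A) tail, so that list gives no check on it. Whether library preparation or RNA handling contributed to its difference was not tested. LCN2 (ENSSSCG00000005638) had 7.42 and 2.49 FPKM, a ratio of 2.98. CRABP2, which binds retinoic acid in the cell, had 8.58 and 2.87 FPKM, and RDH5, a retinol dehydrogenase, had 2.495 and 0.668. S100A4, a calcium-binding protein, had 15.1 and 5.67 FPKM, and DOK6, an adaptor of receptor tyrosine kinases, had 5.81 and 1.86. POLR2F, a subunit of RNA polymerase II, had 3.44 and 0.832 FPKM, and the secreted ligand WNT5B had 1.89 and 0.440. The small nucleolar RNA genes SNORA29 and SNORA8 had 24.1 and 19.5 FPKM in control and were listed at 0 in iron dextran. Among IDs without a symbol, ENSSSCG00000007978 had 359 FPKM in control and 872 in iron dextran, ENSSSCG00000026167 had 19.9 and 47.2, ENSSSCG00000004682 had 55.6 and 6.57, and ENSSSCG00000029058 had 33.3 and 8.48. These 4 were chosen after their values had been seen.

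**Figure D2:**
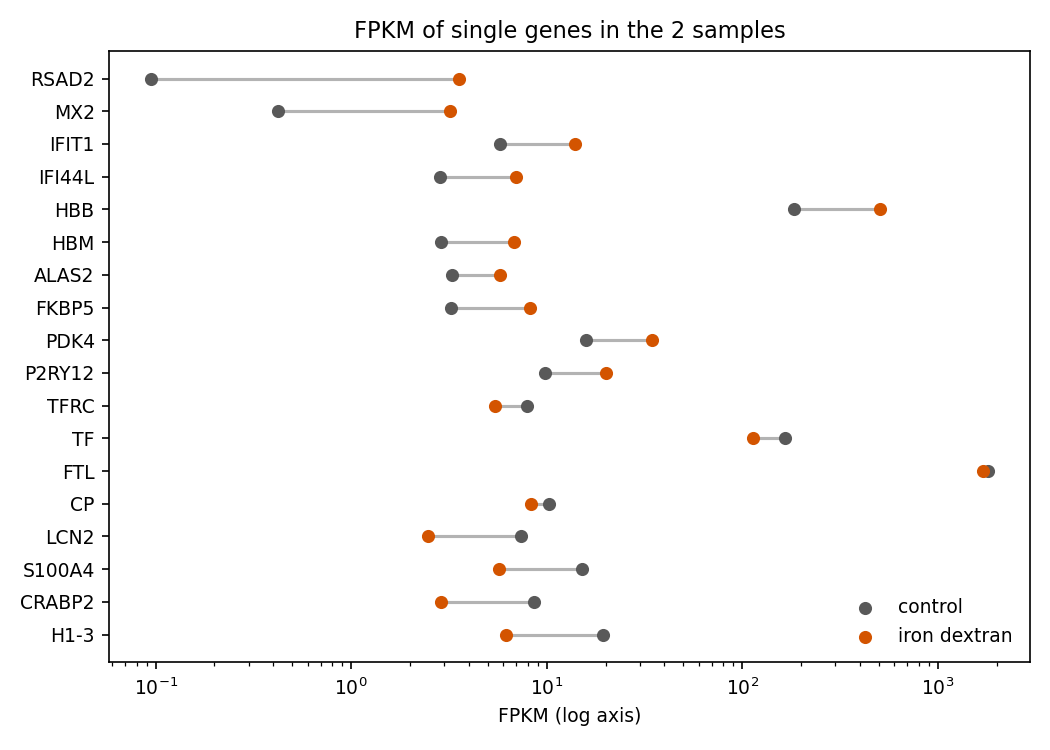
FPKM (log axis) of 18 named genes in the control sample (grey) and the iron dextran sample (orange), 1 value per sample and gene, joined by a line. RSAD2, MX2 and HBB lie to the right in iron dextran, and TFRC, LCN2, S100A4, CRABP2 and H1-3 lie to the left, while FTL differs little at 1806 and 1699 FPKM.

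The median of the iron handling list did not stand apart from those of matched random lists. The list was not split by the direction in which iron would move each transcript. Its median therefore cannot show whether these genes responded to iron. Of 32 listed genes, 11 were measured, with 3 above 0 and 8 below. None of the 11 measured members was at least 1.5-fold higher in iron dextran, and 1, LCN2, was at least 1.5-fold lower. The median log2 difference was −0.11, at percentile 8.65 of random lists matched on expression. TFRC (ENSSSCG00000011848), which takes iron-loaded transferrin into cells, had 7.98 FPKM in control and 5.43 in iron dextran, a log2 difference of −0.48. TF (ENSSSCG00000011640), transferrin itself, had 165 and 113 FPKM, a log2 difference of −0.54. CYBRD1, a ferric reductase, had 3.37 and 4.53 FPKM. FTL, the ferritin light chain, had 1806 and 1699 FPKM, and the ferroxidase CP had 10.3 and 8.36. SLC40A1, the iron exporter ferroportin, was listed at 0 in both samples, and FTH1, SLC11A2, HAMP, HMOX1 and MBP had no ID paired with that symbol. The 13 haem metabolism genes had a median of −0.04 (percentile 36.2), with BLVRB at 8.87 and 11.2 FPKM. The 12 genes of iron-sulfur cluster assembly had a median of −0.05 (percentile 33.4), with CIAO3 at 38.4 and 30.6 FPKM. The 18 hypoxia targets, whose regulator is degraded by iron-dependent enzymes, had a median of 0.03 (percentile 80.9), with PFKFB3 at 3.18 and 4.13 FPKM. The 18 antioxidant and ferroptosis genes had a median of −0.02 (percentile 75.8), with the cystine transporter SLC7A11 at 0.702 and 1.35 FPKM. On the log2(FPKM + 1) scale, none of the members of these last 4 lists was 1.5-fold higher or lower. With the same column total, the medians of the iron handling (0.01), haem (0.07), iron-sulfur (0.06) and antioxidant (0.08) lists turned above 0; centring by expression bin also turned the antioxidant list (0.02), and the hypoxia list turned below 0 with it and at a mean FPKM of at least 5 (−0.03).

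The interferon response genes formed the group with the most members past 1.5-fold. All 19 measured members were above 0 on the difference scale, 14 were at least 1.5-fold higher in iron dextran and none was lower by that much. Their median log2 difference was 0.85, above the medians of all 10000 matched random lists. Besides RSAD2 and MX2, IFIT1, which binds viral RNA, had 5.80 FPKM in control and 13.9 in iron dextran, and IFI44L had 2.85 and 6.98. Another 8 members of the list lay below a mean FPKM of 1, among them TAP1, PSMB8 and PSMB9, which were listed at 0 in both samples, and OASL, the 1 member below 0 (0.335 FPKM in control and 0.106 in iron dextran). Microglia and macrophage markers had a median of 0.34, also above all random lists, with 10 of 11 members above 0. On the log2(FPKM + 1) scale 1 member, P2RY12, a receptor of microglia, was at least 1.5-fold higher (9.80 and 20.05 FPKM). CX3CR1 had 11.3 and 15.7 FPKM, CTSS 5.68 and 7.85, and CSF1R 1.59 and 2.40. The 4 measured leukocyte markers had a median of 0.11 (percentile 64.2), with PTPRC at 1.09 and 1.95 FPKM and NKG7 at 1.18 and 1.35. Of 12 inflammation genes, with a median of 0.05 (percentile 66.4), PTGS2 (1.11 and 2.40 FPKM) and CCL2 (1.81 and 3.25) were at least 1.5-fold higher and LCN2 was lower; the median turned below 0 at a mean FPKM of at least 5 (−0.11) and without a filter.

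All 3 measured erythroid genes were at least 1.5-fold higher in iron dextran, with a median of 1.003 (percentile 99.9). Besides HBB, the globin HBM had 2.89 FPKM in control and 6.80 in iron dextran. ALAS2, the erythroid enzyme of the first step of haem synthesis, had 3.29 and 5.78 FPKM. Without the filter on low values the median was 0.40.

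Among markers of brain cells, oligodendrocyte and myelin genes had a median of −0.22, below those of random lists (percentile 0.03). It was −0.10 with the same column total and −0.13 after centring by expression bin. Of 12 members, 11 were below 0 and none was past 1.5-fold. TF is shared by this list and iron handling, the connexin GJB1 had 24.9 FPKM in control and 17.9 in iron dextran, and OPALIN had 257 and 197. Meninges and fibroblast markers had a median of −0.29 (percentile 0.02, and −0.18 with the same column total) and an interval of the median from −0.48 to 0.14. Of 8 members, 6 were below 0 and none was past 1.5-fold on the log2(FPKM + 1) scale. COL1A2, a fibrillar collagen, had 6.87 and 5.07 FPKM, COL3A1 had 8.92 and 6.96, and the transporters SLC13A4 and SLC6A13 had 2.05 and 1.18 FPKM and 5.395 and 3.82 FPKM. The lists of cell types and neighbouring tissues that follow lay inside the central 95% of random lists. The 7 oligodendrocyte precursor markers had a median of −0.13 (percentile 11.1), with BCAS1 at 294 and 218 FPKM. That median was −0.0069 with the same column total and −0.0583 after centring by expression bin. The 11 astrocyte markers had a median of −0.01 (percentile 88.9), with SLC1A3 at 116 and 143 FPKM, and the 9 neuronal markers had a median of −0.04 (percentile 95.3), with SYN1 at 270 and 236. The 7 endothelial markers had a median of −0.08 (percentile 10.6), the 8 pericyte and smooth muscle markers −0.09 (percentile 8.52), the 7 choroid plexus markers −0.06 (percentile 21.8) and the 4 ependymal markers −0.21 (percentile 3.19). TEK had 1.81 and 1.203 FPKM, DES 2.75 and 1.86, TTR 19.9 and 24.2, and FOXJ1 8.89 and 6.14. For the subfields of the hippocampus, the median was 0.23 (percentile 97.1; 0.0278 at a mean FPKM of at least 5 and 0.0528 without a filter) over 6 dentate granule markers, −0.01 (percentile 46.5) over 4 CA1 markers and −0.11 (percentile 10.15) over 7 markers of CA3 and CA2. C1QL3, of the dentate list, had 11.5 and 16.5 FPKM, POU3F1, of the CA1 list, had 12.2 and 16.2, and NECTIN3, of the CA3 and CA2 list, had 11.1 and 8.50. For neighbouring tissue, the median was −0.09 (percentile 7.97) over 9 markers of thalamus and habenula, −0.09 (percentile 17.6) over 6 of striatum and 0.03 (percentile 69.9) over 10 of cortex, with PRKCD at 12.4 and 8.51 FPKM, ADORA2A at 3.69 and 2.29, and CCN2 at 26.2 and 32.7. With the same column total, the medians of the neuronal, astrocyte, endothelial, pericyte, choroid plexus, CA1, CA3 and CA2, thalamic and striatal lists turned above 0, to at most 0.10. At a mean FPKM of at least 5, those of the CA1 (0.01) and striatal (0.13) lists turned above 0 and that of the cortical list below it (−0.04); without a filter the CA1 and striatal (0.05) lists turned, and after centring by expression bin the neuronal, astrocyte (both 0.07) and CA1 (0.02) lists did.

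**Figure D3:**
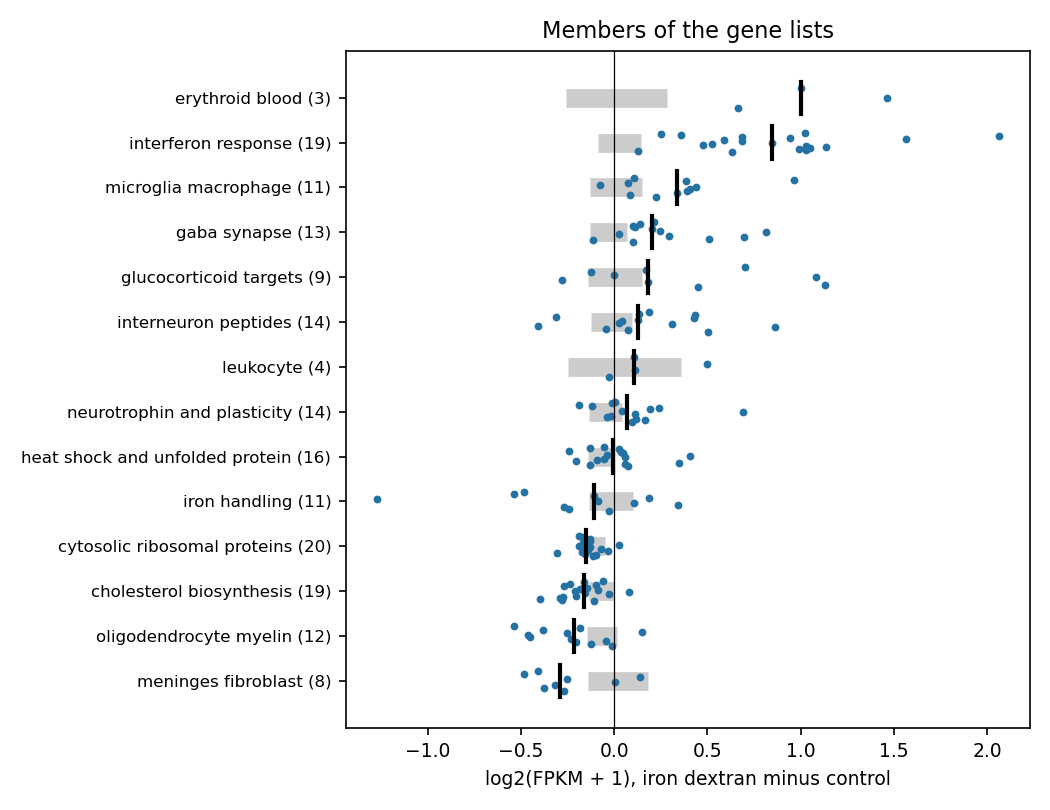
Difference in log2(FPKM + 1), iron dextran minus control, of each measured member (points) of the 12 lists outside the central 95% of random lists and of the iron handling and leukocyte lists; black bars are list medians, grey bars the central 95% of medians of matched random lists, and numbers in parentheses are measured members. The interferon median of 0.85 and the microglial median of 0.34 lie above their grey bars, and those of oligodendrocytes (−0.22) and meninges (−0.29) lie below.

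Synaptic genes of inhibitory transmission had a median above those of random lists. The 13 GABA synapse genes had a median of 0.20, above all random lists, with 12 above 0 and 2 at least 1.5-fold higher, the receptor subunits GABRG1 (4.23 and 8.17 FPKM) and GABRA3 (11.3 and 19.0). GABRA2 had 7.64 and 11.3 FPKM. The 14 interneuron genes had a median of 0.13 (percentile 99.4; interval from −0.04 to 0.43), with 11 above 0 and 3 below, and 1, the cannabinoid receptor CNR1, was at least 1.5-fold higher (3.04 and 6.36 FPKM); PENK had 123 and 166. CORT (8.29 and 6.01 FPKM) and PVALB (105 and 84.4) were among the 3 below 0 and were chosen after their values had been seen. The 14 neurotrophin and plasticity genes, 4 of them also neuronal markers, had a median of 0.07 (percentile 99.2; interval from −0.04 to 0.19), and 1, the BDNF receptor NTRK2, was at least 1.5-fold higher (21.4 and 35.2 FPKM). BDNF itself had 12.7 and 13.7 FPKM. The 22 glutamate synapse genes had a median of 0.05 (percentile 86.5), with GRM5 (3.09 and 6.14 FPKM) and CAMK2A (1.995 and 3.93) at least 1.5-fold higher, GRIA2 at 14.6 and 21.6, and GRIN2B at 1.72 and 0.850. The 18 voltage-gated channels had a median of 0.10 (percentile 88.1), with KCND2 at 6.64 and 8.67 FPKM, and the median turned below 0 at a mean FPKM of at least 5 (−0.12). The 9 monoamine and acetylcholine genes had a median of 0.03 (percentile 66.3), with HTR2C at 1.45 and 1.999 FPKM, and the 12 immediate early genes of neuronal activity had a median of 0.11 (percentile 89.3), with FOS at 7.21 and 8.87 FPKM. With the same column total the GABA synapse, interneuron and neurotrophin medians were 0.32, 0.25 and 0.18, and without a filter the neurotrophin median was 0.02.

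Glucocorticoid-responsive genes had a median of 0.18 (percentile 99.1; 0.30 with the same column total and 0.09 at a mean FPKM of at least 5), and 3 of 9 were at least 1.5-fold higher in iron dextran. FKBP5, a co-chaperone of the glucocorticoid receptor, had 3.24 FPKM in control and 8.26 in iron dextran. PDK4, which inhibits pyruvate dehydrogenase, had 15.9 and 34.8 FPKM, and the transcription factor ZBTB16 had 2.03 and 3.93. Of the 9, 6 were above 0 and 3 below, NFKBIA (29.4 and 24.1 FPKM), SGK1 (47.7 and 43.6) and PER1 (31.11 and 31.08), and the interval of the median ran from −0.13 to 1.08. The 6 thyroid hormone genes had a median of 0.12 (percentile 96.2), with SLCO1C1 at 16.5 and 20.9 FPKM. Of 16 heat shock and unfolded protein genes, 8 were above 0 and 8 below, with DNAJB1 at 20.9 and 26.8 FPKM and HSP90AA1 at 1420 and 1231. Their median of −0.01 was at percentile 97.8, and its direction turned when the columns were scaled to the same total (0.11) or centred by expression (0.07).

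Cholesterol biosynthesis genes had a median of −0.16, below those of random lists (percentile 0.15). It was −0.0454 with the same column total. Of 19 members, 18 were below 0 and none was past 1.5-fold. DHCR7, of the last steps of the pathway, had 37.1 and 27.9 FPKM, FDFT1, the squalene synthase, had 142 and 116, and FDPS had 226 and 186. Cytosolic ribosomal protein genes had a median of −0.15 (percentile 2.28; −0.0288 with the same column total and −0.0462 after centring by expression bin), with 19 of 20 below 0 and RPL38 at 796 and 644 FPKM. The 27 nuclear genes of oxidative phosphorylation had a median of −0.10 (percentile 28.3), with COX7A2 at 882 and 742 FPKM. That median was 0.02 with the same column total and −0.0054 after centring by expression bin. The 13 mitochondrially encoded genes had a median of −0.14 (percentile 9.06; −0.022 with the same column total and −0.0395 after centring by expression bin), with COX3 at 53381 and 46969 FPKM. The 16 cell cycle and neurogenesis genes had a median of 0.01 (percentile 35.5), with SOX11 at 3.78 and 5.16 FPKM, and it turned below 0 with columns centred on their median and at a mean FPKM of at least 5 (−0.03). The lists of pituitary and hypothalamus and of histones without a poly(A) tail had 1 and 0 measured members and were not compared with random lists. The linker histone named among the lower genes was measured but was not on the histone list. The lack of measured members therefore describes that list and not all histones.

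Of 40 lists compared with random lists, 8 had a median above the central 95% of random lists and 4 below it; genes of a list can vary together between any 2 samples, so these numbers are not set against chance. The heat shock, ribosomal, neurotrophin and glucocorticoid lists each came inside these limits under at least 1 alternative, and scaling to the same column total moved the median of all genes to 0.10. Random lists were matched on mean expression and not on transcript length. Whether the 2 samples differed by transcript length or RNA quality was not tested, so such a difference is not excluded for any list.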

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

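Centring by expression bin, leaving out genes listed at 0 and counting genes with a symbol alone were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because each sample had 1 column of values; for the same reason, leaving out a column, the limma fits over columns and the rule that allows overlap between columns were not run. Against 93 genes higher and 53 lower in iron dextran, the counts were 178 and 108 with a pseudocount of 0.1, 195 and 118 with 0.01, 34 and 25 at a mean FPKM of at least 5, 55 and 29 without genes listed at 0, 23 and 10 over genes with a symbol, 310 and 185 at 1.5-fold and 30 and 21 at 4-fold. These follow from the construction of the settings, which change the genes that enter, the weight of low values or the fold; under no filter, the 3 rescalings and the centring both counts stayed within 1.5 times. The interferon, microglia, GABA synapse, interneuron, erythroid, oligodendrocyte, meninges and cholesterol lists kept their side of the percentile limits under every alternative that gave a value (erythroid genes gave none at a mean FPKM of at least 5). The ribosomal list moved to percentile 2.75 (pseudocount of 0.01), 3.2 (mean FPKM of at least 5) and 2.55 (TMM). The neurotrophin list moved to 93.5 without a filter and 87.6 among unmatched random lists, and the glucocorticoid list to 93.65 at a mean FPKM of at least 5. The heat shock list moved to 96.95 without a filter, 97.15 with the same column total, 96.8 after centring by expression bin and 48.45 among unmatched random lists, and its median turned to 0.11 with the same total and 0.0682 after that centring. The erythroid median was 0.40 without a filter. The ribosomal median was −0.17 with columns centred on their median, −0.0288 with the same total and −0.0462 after centring by bin, and the cholesterol median was −0.0454 with the same total. The cause of these shifts in lists was not tested, apart from the same total, which moves the median of all genes to 0.10. Of 358 list medians under alternatives, 342 stayed within the interval of the main median. Of 242 values of the 30 named genes, 214 moved by less than 1.5-fold and 28, at the smaller pseudocounts, by more. The unknown depth leaves open how far low genes such as RSAD2 and MX2 reflect counting error.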

Other observations

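The comparisons with leukocyte markers and antigen presentation genes, the bounds that decide each test, centring by expression bin and leaving out genes listed at 0 were chosen after the results had been seen; the other alternatives were planned. Antigen presentation genes, which interferons also induce in many cells, were added as a list after the interferon genes had been seen. Of its 7 measured members, 2 were above 0 and none passed 1.5-fold on the log2(FPKM + 1) scale. Their median log2 difference was −0.0609 (percentile 22.2). SLA-DQB1, of the class II complex, had 6.23 FPKM in control and 4.01 in iron dextran, TAPBP had 16.6 and 13.6, and ERAP1 had 1.26 and 1.71.

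The higher interferon response genes (median 0.85) were set against 3 explanations. Scaling, the pseudocount or low values do not account for the whole pattern. Over the alternatives run the list median lay between 0.59, at a mean FPKM of at least 5, and 0.95. The lowest bound of its interval was 0.25, while the largest median of all genes was 0.102, with the same column total. For a rise of all interferon-responsive programmes, the measured antigen presentation genes did not rise as the interferon list did. Their median was −0.0609, and the upper bound of its interval, 0.27, which is the highest member, lay below the interferon median. With 7 of 24 listed genes measured, a smaller or partial rise cannot be excluded. TAP1, PSMB8 and PSMB9 could not be read, being listed at 0. More leukocytes in the iron dextran tissue cannot be told apart. Over 4 markers the median log2 ratio without a pseudocount was 0.17, below 0.59, the lower bound of the interferon median. That bound is no firm limit, since more leukocytes need not raise both sets of genes by the same fold. The highest marker, PTPRC, was at 0.84, and microglia also express PTPRC and LCP1. Iron dextran, or an infection or other difference between the animals of the samples, may each lie behind the pattern, and 1 sample per group leaves this untested.

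The higher erythroid transcripts (HBB, HBM and ALAS2) may come from more blood left in the iron dextran tissue, or from more young red cells in the blood. More blood would bring leukocyte transcripts along, and the same 4 markers had a median log2 ratio of 0.17 against 0.81 for the lowest erythroid gene, ALAS2, with a range from −0.03 to 0.84. The highest marker, PTPRC, passed ALAS2 alone and lay below HBB and HBM, whose plain ratios, not on the log2 scale, were 2.76 and 2.35. With 4 low markers, of which microglia also express PTPRC and LCP1, this explanation cannot be told apart from an effect of iron dextran on red cells, which was not tested.

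The low median of the oligodendrocyte genes could have come from the slope of the difference with expression. The median difference was 0.06 at 1 to 5 FPKM and −0.10 at 100 FPKM and above. After centring by expression bin the list median shrank from −0.22 to −0.13, with an interval from −0.39 to −0.0199 that barely excludes 0, so this slope accounts for part of the pattern at most. A smaller share of white matter in the dissected tissue was not tested and stays open beside an effect of iron dextran.

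Rows of the deposited table tended to run from large to small differences, with Spearman's rho of −0.943 between row position and absolute log2 difference across the 12557 genes with a mean FPKM of at least 1 (genes are not independent replicates). There were exceptions, such as SNORA46, listed at 0 in control, in row 1990. Not all exceptions were listed at 0: TF (log2 difference −0.54) was in row 162, ahead of RSAD2 (2.06) in row 373. How the rows were ordered is not known. The last 11479 rows ran by rising gene ID and held all rows listed at 0 in both samples, and 12 of the 27 interferon list genes with a row were among the first 100 rows, of which 52 had a symbol.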
